A study of Homo sapiens with 12 samples.

How the data were processed

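mRNA and miRNA of NCI-H446 cells were measured by Illumina sequencing in 3 DMSO and 3 CAPE libraries each, and each kind was fitted separately with the group as the only term. For mRNA the deposited values were estimated counts per gene symbol, made with kallisto 0.46.1 against GRCh38 after bcl2fastq, per the submitters' processing notes. They are whole numbers as deposited, but 32 to 65 genes per library had a TPM above 0 beside a count of 0, which marks them as rounded estimates. The authors also deposited TPM values per gene, which divide counts by transcript length, from kallisto, and the listed genes sum to 928267 to 947906 TPM per library. How transcripts were summed to genes, and the annotation release, are not given in the sources used here. For miRNA the deposited values were raw counts per mature miRNA in 2888 entries with 2656 names, and the aligner, counter, adapter trimming and handling of reads with several matches are not given in the sources used here. Of 232 entries that repeated a name, the one with the highest total was kept per name, so that reads shared by copies of a miRNA counted once.

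Counts were filtered with edgeR's filterByExpr, scaled with TMM factors and compared by the quasi-likelihood F test (R 4.3.3, edgeR 4.0.16), with Benjamini-Hochberg adjusted p under 0.05 over all features tested. This left 13595 genes and 527 miRNAs. CPM are counts relative to TMM-scaled library sizes, log2 CPM used a prior count of 2, and the SE of a log2 fold change is its size divided by the square root of F. The TMM factor was 0.699 in DMSO 3 and 1.07 to 1.09 in the other mRNA libraries, and DMSO 3 had 16207 genes detected against 17864 to 18587. Counting intervals for ratios of summed miRNA counts are exact 95% Clopper-Pearson intervals and cover counting error only, since the reads carry no molecular identifiers.

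Gene lists (29 for mRNA, 11 for miRNA), 43 pairs of miRNA and host gene, the tests and the naming rule were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of each kind. Of 29 mRNA lists 27 had at least 2 members tested, and the list of nuclear-retained RNAs was not analysed here. Camera passed 15 mRNA lists (8 up, 7 down), of which G2/M and mitosis, cholesterol synthesis and hypoxia targets also passed with an estimated correlation, and 2 miRNA lists, of which the GC-rich list did. fry, which tests whether a list moves one way on balance and not against other genes, passed 5 mRNA lists (G2/M and mitosis, cholesterol synthesis, hypoxia targets, interferon-stimulated genes and immediate-early genes), 25 without DMSO 3, and 2 miRNA lists. The fry adjusted p was 0.0559 for both ATF4 and NF-kB targets, 0.0589 for YAP/TEAD targets and 0.112 for both MYC-activated and heat shock targets. Where a list's signs differed, its direction is not stated: the NRF2 median and mean were -0.19 and -0.07 with camera upward, and the fibroblast median and mean 0.04 and -0.02. The mean of the neuroendocrine miRNA list was 0.00448 and its median 0.21, with camera downward, and for the miR-106b-25 cluster camera was downward beside a median of 0.03. Correlations of host pairs used 100000 permutations, two-sided.

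The rule for named genes had these parts. For mRNA it took MYC and YAP1, and the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 3 and no overlap between the groups. It added, per list, the 2 passing members with the smallest p in each direction, or the member with the smallest p where none passed. For miRNA it took miR-3960, the 5 most abundant, the 8 largest rises and 8 largest falls on the same terms, and the 2 members with the smallest p per list. Anonymous genes and pseudogenes were not named, and some items that the rule takes are not reported here. Coordinates are those of a RefSeq table of GRCh38, in which 26157 of 34886 symbols were found.

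The tests were checked on simulated data drawn from the means, library sizes and fitted dispersions of each comparison, with every gene drawn independently. The dispersions of the 6 mRNA libraries include the spread of DMSO 3, which the simulation shared among all 6. In the data that spread lies mostly in DMSO 3, so the recoveries and false calls with 6 mRNA libraries hold only for evenly spread noise. With 6 mRNA libraries (13595 genes) the test recovered 0 of 67 genes changed 1.5-fold, 0 of 67 changed 2-fold and 34 of 66 changed 4-fold, with 2 false calls. Without DMSO 3 (13919 genes) it recovered 47 of 67, 58 of 67 and 62 of 66, with 10 false calls, and for the 527 miRNAs 38 of 67, 58 of 67 and 63 of 66, with 4 false calls. Of 200 random lists of 25, camera gave a p under 0.05 for 7 with 6 mRNA libraries, 2 without DMSO 3 and 0 for miRNA. Since the simulated genes were independent, this does not show how often lists of correlated genes pass falsely. With an estimated correlation camera gave a p under 0.05 for 0 of the 200 lists in each comparison. That form of the test was thus conservative there, and a call that it loses is weak evidence against a list. The estimated correlation in the real data of 6 mRNA libraries reached 0.945 in the proteasome list.

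Alternatives chosen before the data were examined were DESeq2 size factors (RLE), library totals, no filter, a minimum of 1 CPM for mRNA or 10 CPM for miRNA in 3 libraries, the DESeq2 1.42.0 Wald test with its own size factors and filter, limma-voom, the replicate number as a block, leaving out each library, and limma on log2 TPM with a pseudocount of 1 or 0.1 and a minimum of 1 TPM in 3 libraries, or with a pseudocount of 1 and no minimum. Chosen after seeing the data were library quality weights, removal of the trend with transcript length, alone and with DMSO 3 left out, robust dispersion, the DESeq2 test on the genes and TMM factors of edgeR with no further filter, summing of repeated miRNA names and leaving out miR-21-5p. Relative transcript length was the ratio of count to TPM in the 5 mRNA libraries other than DMSO 3, scaled to 1 at the median gene. miRNA target sites and GC content were not analysed here.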

Results

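RNA was profiled in NCI-H446, an established human small cell lung cancer line, after 8 h with 40 µM caffeic acid phenethyl ester (CAPE), a phenolic ester found in propolis and known as an inhibitor of NF-kB, or with the same volume of its solvent dimethyl sulfoxide (DMSO). Messenger RNA and microRNA (miRNA) were sequenced separately, with 3 DMSO and 3 CAPE libraries of each kind, 12 libraries in 4 groups. The mRNA libraries held 17569997 to 20917508 estimated counts over 34886 gene symbols, the most in DMSO 3. The miRNA libraries held 4637576 to 8933025 counts over 2656 mature names, with 7387387, 8174713 and 8933025 in DMSO and 5448086, 6134006 and 4637576 in CAPE. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

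One mRNA library stood apart from the other 5. Of the 13595 genes tested, 2858 were at least 2-fold lower and 2836 at least 2-fold higher in DMSO 3 than in the mean of DMSO 1 and DMSO 2. Genes in its shortest decile of relative transcript length deviated by a median of 1.45 on the log2 scale and those in its longest decile by -1.04. The fit without this library is therefore given beside MYC, YAP1, the 20 largest changes and most gene lists.

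**Figure D1:**
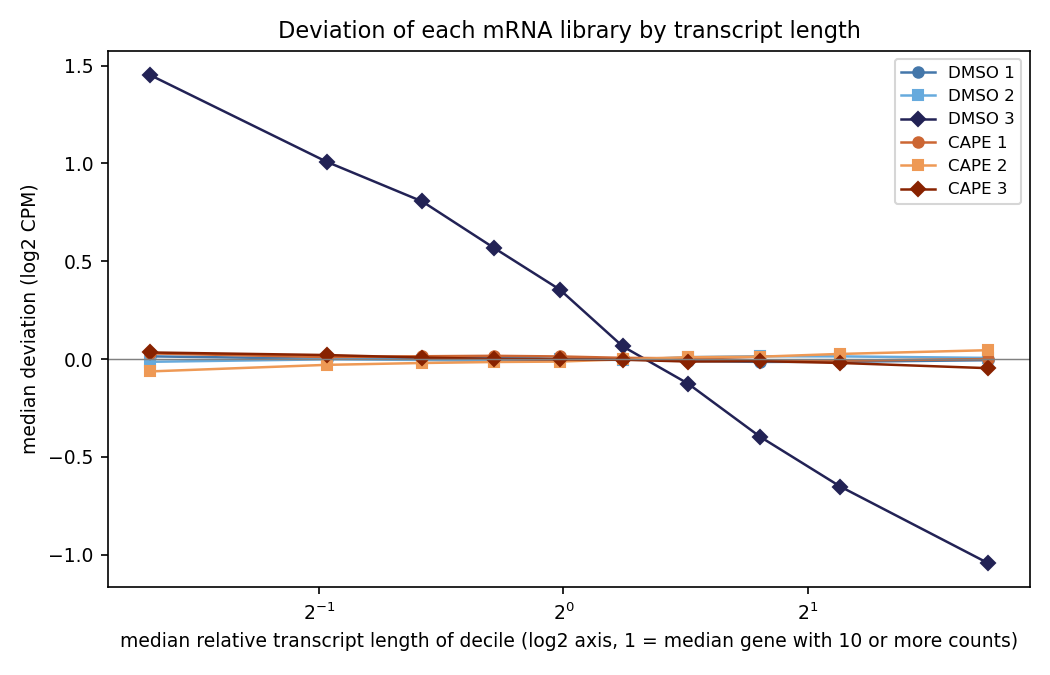
Median deviation of each mRNA library from the other libraries of its group (vertical axis, log2 CPM) against the median relative transcript length of 10 equal groups of genes (horizontal axis, log2 scale, 1 is the median gene with 10 or more counts), with DMSO 3 left out of the reference of DMSO 1 and DMSO 2. DMSO 3 falls from 1.45 in the shortest genes to -1.04 in the longest, while CAPE 2, the widest of the other 5 lines, runs from -0.06 to 0.05.

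The mRNA comparison asked which genes CAPE changed within 8 h. The largest rises that met the naming rule were in EPHA3, an ephrin receptor tyrosine kinase (0.968 ± 0.20 CPM in DMSO, 15.4 ± 1.56 in CAPE, SD, n = 3), in PPFIA4, a liprin scaffold protein (8.72 ± 5.81 to 118 ± 6.06 CPM), and in the kinases NIM1K and CDK18, the peptide ligase RIMKLA and the interferon-induced IFIT2. GDF15, a stress-induced cytokine, rose from 4.33 ± 2.18 to 37.5 ± 4.62 CPM, and EGR1, an immediate-early transcription factor, from 5.47 ± 0.594 to 45.2 ± 18.7 CPM. The largest falls under the same rule were in PLK1, a mitotic kinase (352 ± 216 to 37.8 ± 2.72 CPM), in PIF1, a DNA helicase, in BMF, a pro-apoptotic BH3-only protein (16.3 ± 1.5 to 2.21 ± 1.01 CPM), and in CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (42.0 ± 17.5 to 6.19 ± 1.30 CPM). GREM1, an antagonist of bone morphogenetic proteins, fell from 79.9 ± 15.5 to 14.0 ± 2.03 CPM. The mitotic genes KIF20A, CCNB1 and PSRC1, RGS3, a regulator of G protein signalling, and AHRR, the repressor of the aryl hydrocarbon receptor, completed the 10 largest falls, and ADM2, a secreted peptide, and SH3D21 the 10 largest rises. Log2 fold changes of these 20 genes ran from 2.97 to 3.98 among the rises and from -3.22 to -2.06 among the falls, with edgeR adjusted p from 0.00284 to 0.0498. All 20 passed in the same direction without DMSO 3, at 2.59 to 3.83 and -3.39 to -1.80. The rule's demand for no overlap between the groups all but fixed this direction, and 5731 of 13919 genes passed in that fit. PLK1 measured 602 CPM in DMSO 3 against 224 and 231 in the other DMSO libraries, and without DMSO 3 its log2 fold change was -2.59, smaller in size than those of PIF1 (-3.39), CYP1B1 (-3.07), BMF (-2.89) and GREM1 (-2.67).

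In all, 265 genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 203 higher and 62 lower with CAPE, of which 184 and 57 changed at least 2-fold. Without DMSO 3, 5731 of 13919 genes passed, 2836 higher and 2895 lower, and 795 of them changed at least 2-fold (610 higher, 185 lower). All 265 genes were among the 5731, in the same direction. Counts of list members without DMSO 3, given below, are to be read against these shares of all genes. The count was 9 without DMSO 1, 17 without DMSO 2 and 6 without CAPE 2, and 0 without CAPE 1 or CAPE 3, where 1178 and 1099 genes had an unadjusted p under 0.05. With the DESeq2 Wald test the count was 857 with its own filter and size factors (21660 genes fitted), and 991 on the same 13595 genes and TMM factors.

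MYC and YAP1 are named in the title of the series. MYC, the transcription factor at chromosome 8, 127735434 to 127742951 (GRCh38), measured 581 ± 156 CPM in DMSO and 409 ± 14.1 CPM in CAPE (SD, n = 3), a log2 fold change of -0.51 (SE 0.22) that did not pass (edgeR adjusted p = 0.325). The DMSO libraries held 484, 499 and 760 CPM, the last in DMSO 3. Without DMSO 3 MYC fell by 0.27 on the log2 scale (SE 0.04, edgeR adjusted p = 1.07e-04). YAP1, the Hippo pathway coactivator at chromosome 11, 102110447 to 102233424, measured 145 ± 53.4 CPM in DMSO and 167 ± 1.93 CPM in CAPE, with a log2 fold change of 0.20 (SE 0.30, edgeR adjusted p = 0.690). DMSO 3 held 83.5 CPM of YAP1 against 169 and 182 in the other DMSO libraries, and without it the log2 fold change was -0.08 (SE 0.05, adjusted p = 0.187). No change of YAP1 mRNA passed in either fit, and its sign turned with this library.

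**Figure D2:**
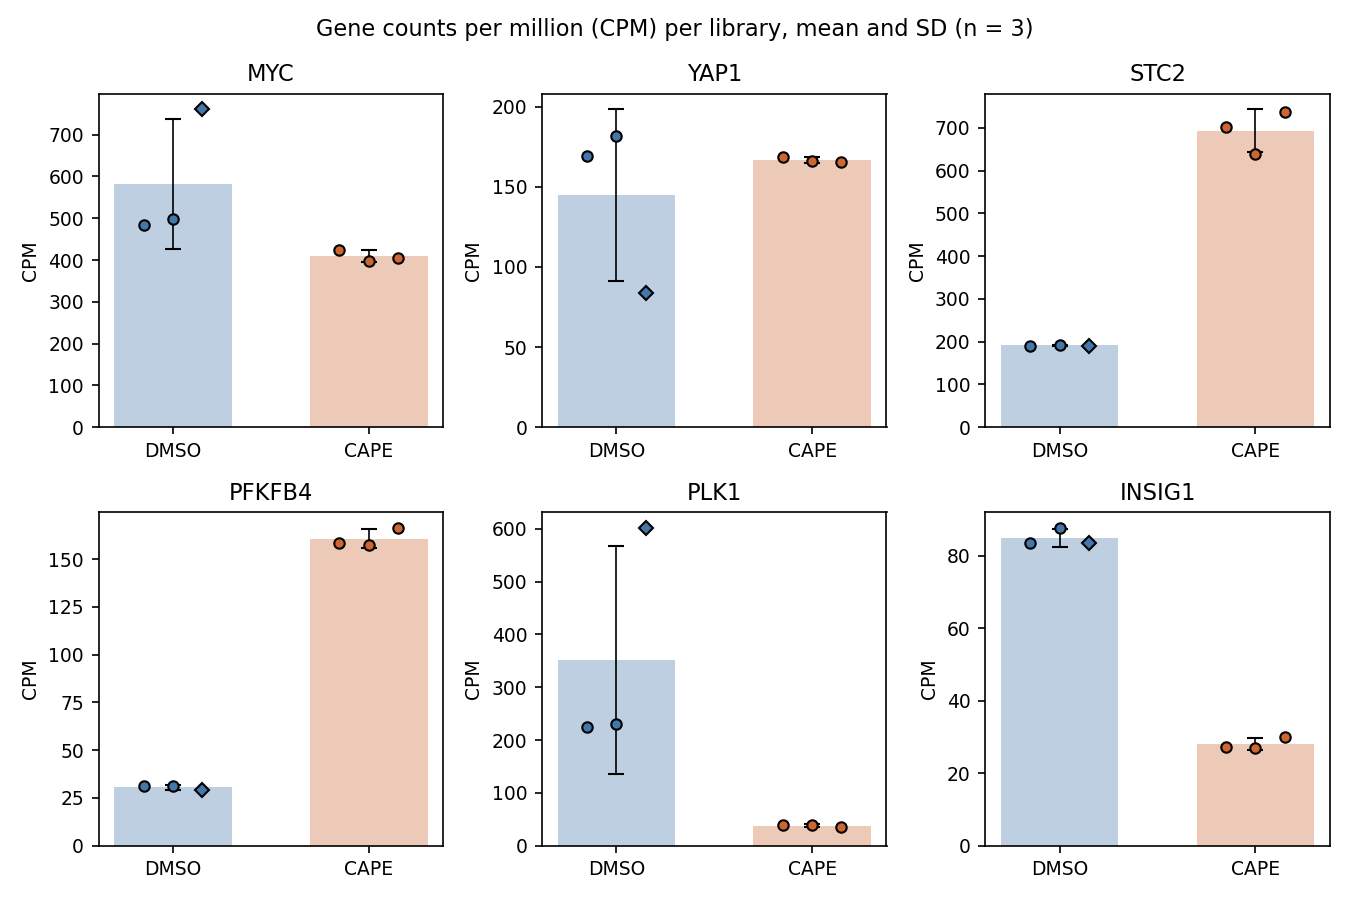
CPM of 6 genes (vertical axis, starting at 0) in the 3 DMSO and 3 CAPE mRNA libraries, with bars for group means, error bars for the SD (n = 3), points for single libraries and a diamond for DMSO 3. STC2 and PFKFB4 are higher and PLK1 and INSIG1 lower in all 3 CAPE libraries, while DMSO 3 holds the highest MYC value (760 CPM) and the lowest YAP1 value (83.5 CPM).

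Of 24 tested genes of the ATF4 integrated stress response, which is set off by amino acid shortage and unfolded proteins, 10 rose and none fell (14 rose when adjusted over the list alone). Their median log2 fold change was 1.09, and the group stood above other genes in limma's camera test at a preset correlation (adjusted p = 2.43e-09) but not with an estimated correlation (adjusted p = 0.327, and 0.209 without DMSO 3). STC2, a secreted glycoprotein, rose from 191 ± 1.54 to 693 ± 50.4 CPM, and VLDLR, a lipoprotein receptor, from 25.7 ± 3.51 to 104 ± 1.72 CPM. Without DMSO 3, 23 of 25 members were higher and 1 lower, with a median of 1.53. In DMSO 3 the members lay a median of 0.93 above DMSO 1 and DMSO 2 on the log2 scale. Chaperones and degradation factors of the endoplasmic reticulum had 1 passing member of 20, DNAJB9 (6.74 ± 0.719 to 16.0 ± 1.30 CPM), and 5 when adjusted over the list alone (camera adjusted p = 3.55e-04, and adjusted p = 0.299 with an estimated correlation). Without DMSO 3, 19 of these 20 were higher, with a median of 0.43, and DMSO 3 deviated by a median of 0.35.

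Of 21 tested hypoxia (HIF) target genes 8 rose and none fell (14 rose when adjusted over the list alone), with a median log2 fold change of 1.01 (camera adjusted p = 4.07e-10, and adjusted p = 0.0255 with an estimated correlation). PFKFB4, a regulator of glycolysis, rose from 30.5 ± 1.27 to 161 ± 4.95 CPM, and SLC2A3, a glucose transporter, from 21.5 ± 2.49 to 62.4 ± 2.68 CPM. Without DMSO 3, 20 of the 21 were higher and none lower, with a median of 1.15, but the call with an estimated correlation was lost (adjusted p = 0.209). DMSO 3 lay a median of 0.47 above the other DMSO libraries in this list. ENO2, the neuronal enolase of glycolysis listed here among neuroendocrine markers, rose from 43.5 ± 8.89 to 178 ± 9.22 CPM (log2 fold change 2.03, and 2.21 without DMSO 3) and was the only one of 6 tested neuroendocrine members to pass (camera adjusted p = 0.264).

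Immediate-early genes, which respond to signalling within minutes, had 9 of 22 members higher and none lower (12 higher and 2 lower when adjusted over the list alone), with a median log2 fold change of 1.07. FOSB, a subunit of the transcription factor AP-1, rose from 2.53 ± 0.258 to 11.8 ± 1.22 CPM and ATF3, which is in the ATF4 list as well, from 7.49 ± 2.28 to 50.7 ± 3.84 CPM. Camera gave an adjusted p of 1.25e-06, and an adjusted p of 0.327 with an estimated correlation. Without DMSO 3, 18 of 23 were higher and 2 lower, and DMSO 3 deviated from the other DMSO libraries by a median of 0.59. NF-kB targets had 5 of 23 members higher and none lower (10 higher and 1 lower when adjusted over the list alone), with a median of 0.67 (camera adjusted p = 2.80e-04, and adjusted p = 0.299 with an estimated correlation). Among them TRAF1, a signalling adaptor, rose from 3.71 ± 0.417 to 12.7 ± 1.31 CPM and TNFAIP3, a feedback inhibitor of NF-kB, from 35.1 ± 9.40 to 113 ± 2.03 CPM. Without DMSO 3, 16 of the 23 NF-kB targets were higher and none lower, and DMSO 3 deviated by a median of 0.39. Interferon-stimulated genes had 4 of 20 members higher (6 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00155, and adjusted p = 0.182 with an estimated correlation). IFIT3 rose from 8.33 ± 0.616 to 41.9 ± 4.10 CPM and IFIT2 from 12 ± 3.71 to 117 ± 12.8 CPM. Without DMSO 3 the interferon list had 12 members higher and 2 lower.

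Genes of G2/M and mitosis fell as a group. Of 24 tested members 9 were lower and none higher (18 lower when adjusted over the list alone), with a median log2 fold change of -1.48 (camera adjusted p = 4.08e-16, and adjusted p = 0.0187 with an estimated correlation). KIF20A, a kinesin of cytokinesis, fell from 239 ± 65.1 to 39.7 ± 1.57 CPM, CCNB1, the mitotic cyclin, from 396 ± 195 to 66.7 ± 3.68 CPM, and BUB1B, a spindle checkpoint kinase, from 205 ± 32.7 to 78.8 ± 3.75 CPM. Without DMSO 3 all 24 were lower, with a median of -1.27. The call with an estimated correlation, a form that was conservative in the simulation, was lost with fewer libraries (adjusted p = 0.209). DMSO 3 deviated by a median of -0.05 in this list, but single members lay far to either side. CCNB1 measured 621 CPM in DMSO 3 against 286 and 282 in the other DMSO libraries, and BUB1B 167 against 219 and 228. No member of the G1/S and DNA replication list passed, of 26 tested, whether adjusted over all genes or over the list alone (median -0.18, camera adjusted p = 0.341). CDC6, a replication licensing factor, measured 139 ± 11.6 CPM in DMSO and 203 ± 0.543 in CAPE. Without DMSO 3, 10 of these 26 were higher, CDC6 among them, and 3 lower, and the median was 0.05 (camera adjusted p = 0.196).

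Of 21 tested genes of cholesterol synthesis and uptake 3 fell and none rose, and 15 fell when adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 2.43e-09, and adjusted p = 0.0285 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, fell from 84.9 ± 2.45 to 28.0 ± 1.62 CPM. Without DMSO 3, 20 of the 21 were lower and none higher, with a median of -0.61, but the call with an estimated correlation was lost (adjusted p = 0.149). In this list DMSO 3 lay a median of 0.56 above the other DMSO libraries.

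Targets activated by MYC, largely factors of ribosome production, had no passing member of 27 in the 6-library fit, whether adjusted over all genes or over the list alone, with a median log2 fold change of -0.80 (camera adjusted p = 1.25e-06, and adjusted p = 0.355 with an estimated correlation). In DMSO 3 these genes lay a median of 1.11 above the other DMSO libraries. Without DMSO 3, 22 of the 27 were lower and 1 higher, with a median of -0.36, and POLR1B, a subunit of RNA polymerase I, fell by 0.55 on the log2 scale (SE 0.05, edgeR adjusted p = 9.67e-07). Heat shock (HSF1) targets likewise had none of 22 passing in the 6-library fit (median -0.76, camera adjusted p = 3.55e-06, and adjusted p = 0.352 with an estimated correlation) and 17 lower and 2 higher without DMSO 3 (median -0.40). HSPA1B, an inducible chaperone whose reads cannot be cleanly separated from those of its near-identical neighbour HSPA1A, fell by 1.11 on the log2 scale without DMSO 3 (SE 0.07, edgeR adjusted p = 1.97e-08). Proteasome subunits had none of 31 passing with all 6 libraries (median -0.66, camera adjusted p = 1.19e-05, and adjusted p = 0.564 with an estimated correlation) and 20 lower without DMSO 3, by a median of -0.14. Ribosomal proteins had none of 43 passing (median -0.94, camera adjusted p = 7.96e-05, and adjusted p = 0.564 with an estimated correlation). Without DMSO 3, 11 ribosomal genes were lower and 2 higher, and the median was -0.09. DMSO 3 exceeded the other DMSO libraries by a median of 1.03 in the heat shock list, 1.24 in the proteasome list and 1.77 in the ribosomal list. RPL5, the ribosomal member with the smallest p, measured 5.61 ± 2.98 CPM in DMSO and 12.3 ± 1.16 in CAPE, and may share reads with its pseudogenes.

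NRF2 targets, the antioxidant genes that electrophilic compounds can induce, had no passing member of 26 with either adjustment (median -0.19, camera adjusted p = 0.807). UGDH had the smallest p, with 38.9 ± 6.21 CPM in DMSO and 60.7 ± 3.87 in CAPE. Without DMSO 3, 9 of 27 were higher, UGDH among them, and 3 lower, with a median of 0.07 (camera adjusted p = 0.138). The largest of these rises, named after their values were seen, were in OSGIN1, SLC7A11, HMOX1 and GCLC (log2 fold changes 1.72, 1.16, 1.04 and 0.97). SLC7A11 is in the ATF4 list as well. TKT, AKR1C3 and NQO1 were the 3 lower (-0.31, -0.20 and -0.12), so single members moved more than the median shows. Metallothioneins, zinc- and copper-binding proteins with similar sequences, had none of 5 passing (2 higher when adjusted over the list alone, median 0.95, camera adjusted p = 0.0263, and adjusted p = 0.564 with an estimated correlation). Without DMSO 3 all 5 were higher, with a median of 1.89 (DMSO 3 deviation 1.91), while the camera call was lost without DMSO 1 or DMSO 2 (adjusted p = 0.151 and 0.156). MT1H had the smallest p, at 0.109 ± 0.145 CPM in DMSO and 1.89 ± 1.05 in CAPE. YAP/TEAD targets had 2 of 21 members higher (5 higher and 1 lower when adjusted over the list alone), namely IGFBP3, an insulin-like growth factor binding protein (101 ± 20.7 to 333 ± 12.6 CPM), and GADD45A, a growth arrest and DNA damage gene that is also a p53 target (23.3 ± 1.77 to 47.1 ± 2.94 CPM). The YAP/TEAD median was 0.27 (camera adjusted p = 0.0109, and adjusted p = 0.256 with an estimated correlation), and the camera call was lost without DMSO 3 (7 higher and 3 lower, adjusted p = 0.138). CTGF was among the 7 (log2 fold change 0.67, edgeR adjusted p = 5.04e-06) and CYR61 among the 3 (-0.52, edgeR adjusted p = 1.42e-06). Both were named after their values were seen. The Hippo pathway core had none of 14 passing (2 higher when adjusted over the list alone, camera adjusted p = 0.264). Without DMSO 3 the Hippo list had 2 higher (camera adjusted p = 0.591). WWTR1, the paralogue of YAP1 also called TAZ, was 1 of them, with a log2 fold change of 0.68 (SE 0.06, edgeR adjusted p = 6.20e-07).

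Among p53 targets GADD45A was the 1 passing member of 21 (2 higher when adjusted over the list alone, camera adjusted p = 0.398). Without DMSO 3, 9 p53 targets were higher and 3 lower (camera adjusted p = 0.131), where 2836 of all 13919 genes were higher and 2895 lower. Of 18 pro-apoptotic genes PMAIP1, which encodes the BH3-only protein NOXA, rose from 25.6 ± 5.71 to 79.4 ± 6.67 CPM while BMF fell (2 higher and 1 lower when adjusted over the list alone). The median of that list was 0.13 and its mean -0.06 (camera adjusted p = 0.566). It had 8 higher and 3 lower without DMSO 3 (camera adjusted p = 0.129). No anti-apoptotic gene of 9 passed (1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.341). BCL2L2 had the smallest p there, with 38.0 ± 7.54 CPM in DMSO and 65.1 ± 4.18 in CAPE. Without DMSO 3, 3 anti-apoptotic genes were higher, BCL2L2 among them (log2 fold change 0.62, edgeR adjusted p = 6.14e-06), and 1 was lower, with a list median of 0.04 (camera adjusted p = 0.555). In the autophagy and lysosome list ULK1, the kinase that starts autophagy, rose from 80.3 ± 9.97 to 182 ± 4.0 CPM and was the only passing member of 20 with either adjustment (median -0.27, camera adjusted p = 0.341). In the fit without DMSO 3, 7 were higher and 5 lower (camera adjusted p = 0.555).

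**Figure D3:**
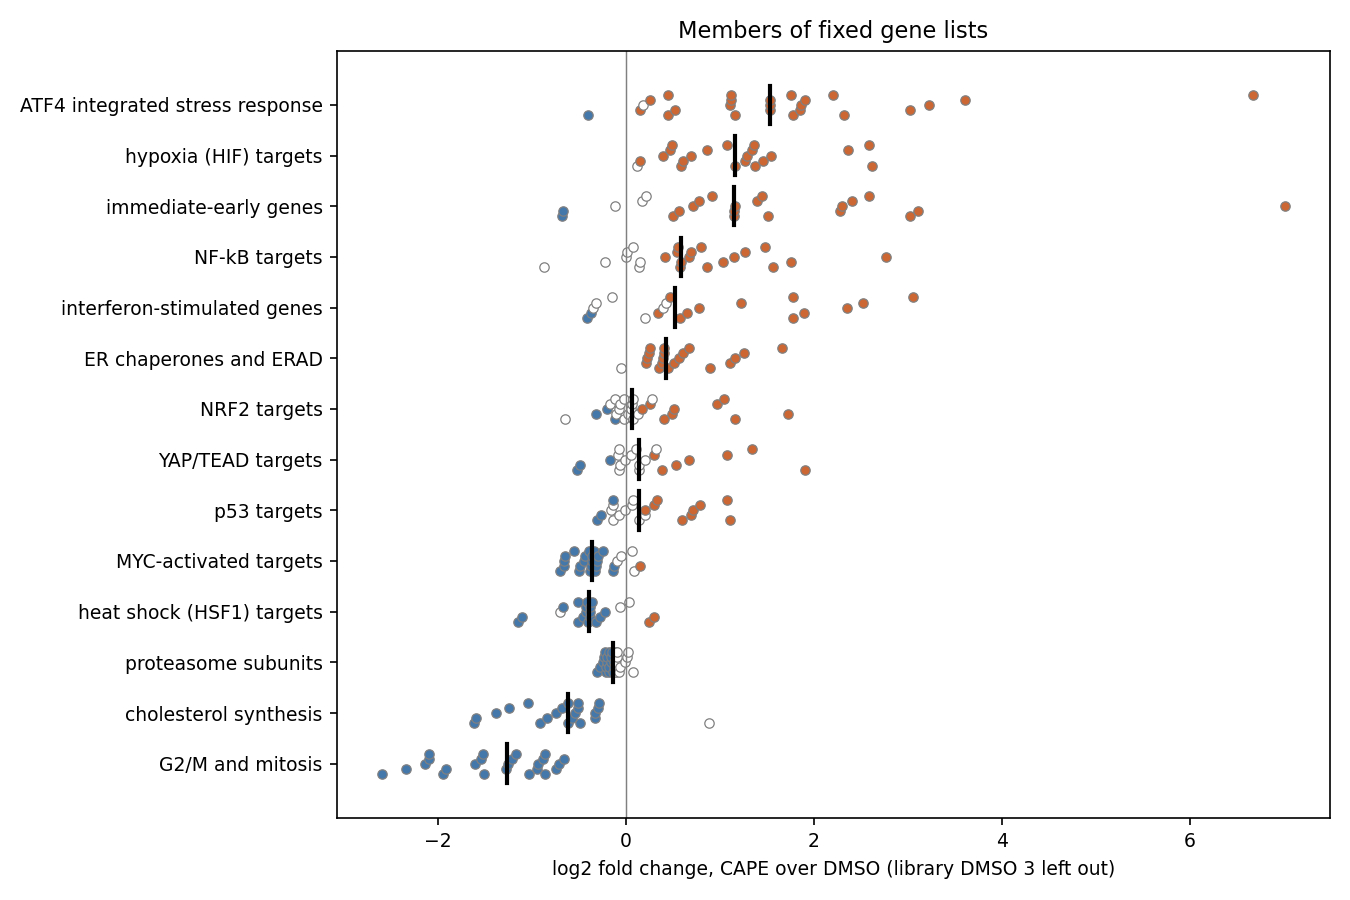
Log2 fold change, CAPE over DMSO, of each tested member of 14 fixed gene lists in the fit without DMSO 3 (horizontal axis), where each point is a gene, orange if higher and blue if lower at an adjusted p under 0.05 and open otherwise, the black bar is the list median, and the vertical spread within a list only separates points. List medians run from 1.53 in the ATF4 list to -1.27 in the G2/M list, where all 24 genes are lower.

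Markers of other cell types and of RNA quality were examined in the same way. No marker passed with all 6 libraries among 7 fibroblast, 2 immune and 6 epithelial genes tested as lists (camera adjusted p = 0.806, 0.576 and 0.20), with either adjustment. COL1A1, PTPRC, PECAM1 and KRT5, the markers with the smallest p, had log2 fold changes of 0.36, 1.31, -0.55 and -0.97 (edgeR adjusted p = 0.327, 0.269, 0.336 and 0.296). DMSO 3 lay a median of 1.96 above the other DMSO libraries in the epithelial list. Leaving it out, 3 epithelial markers were lower, 1 fibroblast marker was higher (COL1A1, edgeR adjusted p = 0.0205) and 1 lower. None of 13 mitochondrially encoded genes passed (median 0.16, camera adjusted p = 0.148). Without DMSO 3, 9 of them were higher, by a list median of 0.20, and the list passed camera (adjusted p = 0.00839) but not with an estimated correlation (adjusted p = 0.364). MT-ND6 had the smallest p of these (491 ± 38.9 CPM in DMSO, 682 ± 22.2 in CAPE). None of 12 replication-dependent histone genes passed (median -0.85, camera adjusted p = 5.27e-04, and adjusted p = 0.519 with an estimated correlation). Without DMSO 3, 3 histone genes were lower. HIST2H2BE had the smallest p there, with a log2 fold change of -0.74, and DMSO 3 lay a median of 0.98 above the other DMSO libraries in this list. Of endothelial markers only PECAM1 was tested with 6 libraries, and neither of 2 passed without DMSO 3 (camera adjusted p = 0.186). With DMSO 3 left out, 15 of 28 lists passed camera at the preset correlation and none with an estimated one, where the smallest adjusted p was 0.149 for cholesterol synthesis. The estimated form was conservative in the simulation and had fewer libraries here. The calls it lost for the G2/M, hypoxia and cholesterol lists are therefore weak evidence that these lists depend on DMSO 3.

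The miRNA comparison asked which miRNAs CAPE changed in the same design. miR-3960, named in the series title and encoded at chromosome 9, 127785833 to 127785923, was counted 1, 0 and 0 times in the DMSO libraries and 10, 13 and 9 times in the CAPE libraries. The sums, 1 and 32, give a normalized ratio of 42.8 with an exact 95% binomial interval of 7.14 to 1741, which covers counting error only, and miR-3960 passed in edgeR's quasi-likelihood test (log2 fold change 4.91, SE 0.74, adjusted p = 0.00125), where at such counts the fitted size depends on the prior count. In CAPE it reached 1.84 ± 0.115 CPM (SD, n = 3). Larger counts lay behind miR-7704, which rose from 3.54 ± 1.12 to 33.7 ± 1.11 CPM (81 and 582 summed counts), miR-1246, from 70.0 ± 21.3 to 166 ± 4.96 CPM, and miR-1290, from 7.05 ± 1.91 to 22.9 ± 1.13 CPM. Both arms of the miR-222 hairpin changed, in opposite directions, with miR-222-5p rising from 17.3 ± 2.87 to 47.4 ± 7.02 CPM and miR-222-3p, the abundant arm, falling from 6998 ± 2371 to 3760 ± 313 CPM. miR-7-5p, an abundant miRNA of neuroendocrine cells, fell from 16961 ± 1577 to 9869 ± 894 CPM, and miR-27b-5p from 226 ± 5.07 to 125 ± 17.8 CPM.

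Of 527 miRNAs tested 62 changed at an adjusted p under 0.05, 39 higher and 23 lower, of which 17 and 1 changed at least 2-fold. Among miRNAs with an average log2 CPM of at least 3, the other largest rises were in miR-378e, miR-30b-3p, miR-30d-3p and miR-320d, with log2 fold changes of 1.13 to 1.44, of which miR-378e and miR-320d have close relatives that can share reads. miR-1292-5p, miR-301a-3p, miR-7706, miR-425-5p and miR-941 fell by 0.79 to 0.87 on the log2 scale. None of the 5 most abundant miRNAs passed, among them miR-21-5p, a widely expressed oncogenic miRNA that took 57.7% ± 0.62 of all counts in DMSO and 53.2% ± 0.78 in CAPE (log2 fold change -0.31, SE 0.12, edgeR adjusted p = 0.122). let-7i-5p, miR-27b-3p, let-7f-5p and miR-30a-5p had log2 fold changes of -0.14, 0.21, 0.17 and -0.40 (edgeR adjusted p = 0.576, 0.384, 0.569 and 0.111). With library totals in place of TMM scaling, which moved the median log2 fold change of all miRNAs to 0.22, the split was 67 higher and 8 lower, and let-7i-5p changed sign. The count of 62 became 30 without DMSO 1, 128 without DMSO 3, 17 without CAPE 2 and 22 without CAPE 3. The miRNA library DMSO 3 deviated most from the rest of its group, with an SD of 0.424 on the log2 scale over 225 miRNAs against 0.117 to 0.306 in the other 5.

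**Figure D4:**
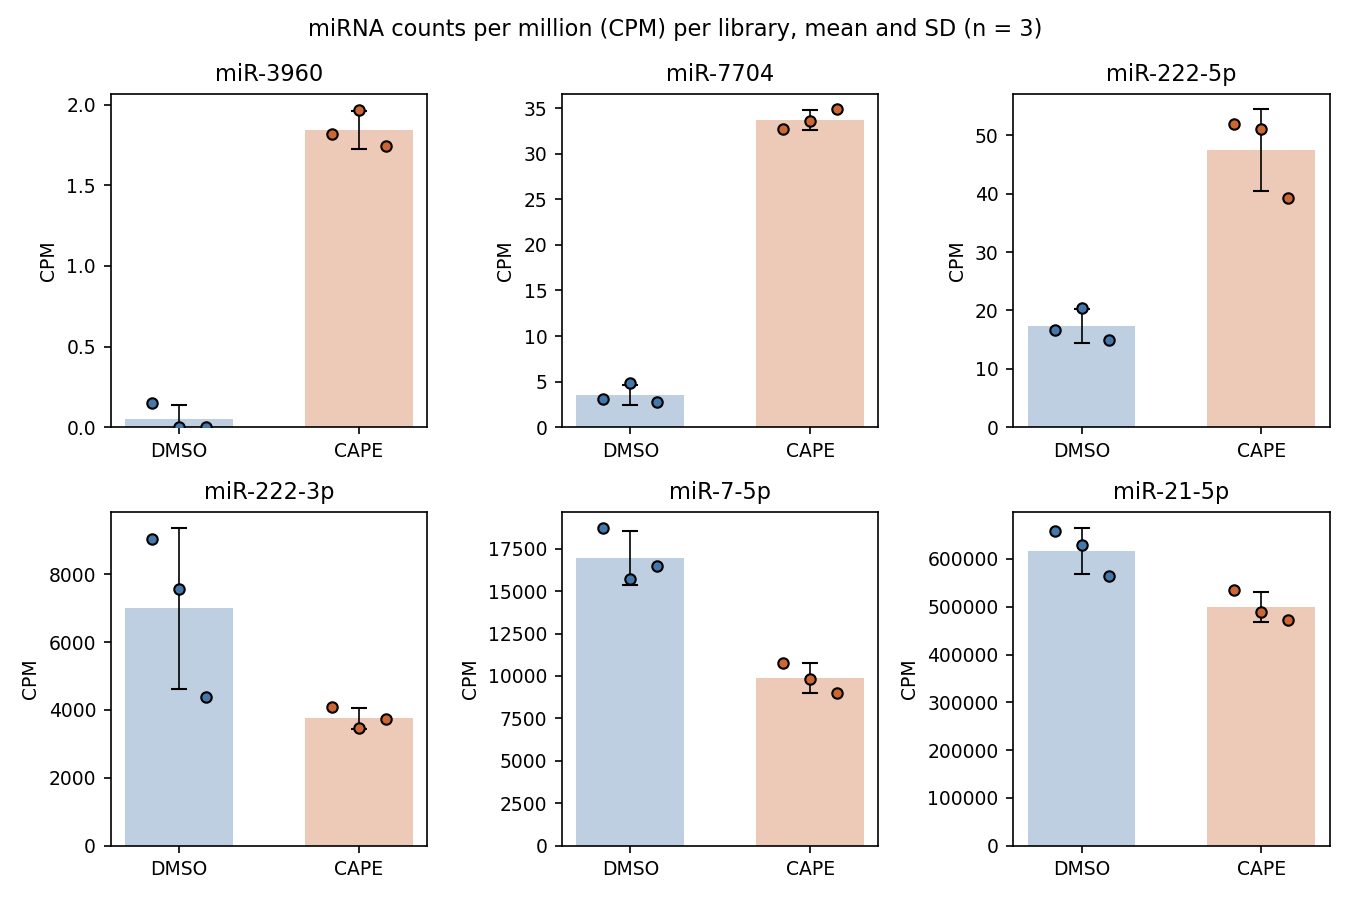
CPM of 6 miRNAs (vertical axis, starting at 0) in the 3 DMSO and 3 CAPE miRNA libraries, with bars for group means, error bars for the SD (n = 3) and points for single libraries. miR-3960 stays under 2 CPM in every library, and miR-21-5p, at 617249 CPM on average in DMSO, did not pass the test.

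Among the 11 miRNA lists, GC-rich names and names that overlap abundant RNAs, a list fixed as a sign of RNA fragments, stood apart. Of 13 tested 9 rose and none fell (10 rose when adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 7.93e-10, and adjusted p = 0.0274 with an estimated correlation). Among those that rose, miR-1260a and miR-1260b had similar summed counts (3475 and 3921 in DMSO, 5321 and 5987 in CAPE). They may share reads, so they may not be separate evidence. miR-3960 belongs to this list, as do miR-7704, miR-1246, miR-1290 and miR-4508, which was counted 2 times in DMSO and 55 times in CAPE (ratio 36.8, exact 95% interval 9.70 to 311). The miR-17-92 cluster, which MYC activates, had 1 of 11 members lower, miR-19a-3p (407 ± 25.1 to 259 ± 8.85 CPM), with either adjustment and a median of -0.16 (camera adjusted p = 0.0441, and adjusted p = 0.294 with an estimated correlation). That median was 0.0219 with library totals, and the camera call was lost without DMSO 2, CAPE 1 or CAPE 2 (adjusted p = 0.060, 0.17 and 0.0575). miR-19b-1-5p had a log2 fold change of -0.42 (edgeR adjusted p = 0.193).

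Of 10 miRNAs that MYC represses, let-7 left out, miR-26b-5p (1811 ± 120 to 2581 ± 83.7 CPM) and miR-29a-3p (1049 ± 102 to 1452 ± 183 CPM) rose and none fell (3 higher and 1 lower when adjusted over the list alone, median 0.20, camera adjusted p = 0.513). In the miR-183-96-182 cluster miR-182-5p (1804 ± 104 to 1212 ± 121 CPM) and miR-96-5p (763 ± 46.9 to 559 ± 67.6 CPM) fell among 4 tested, with either adjustment (camera adjusted p = 0.482). miR-7-5p was the only one of 4 neuroendocrine miRNAs to pass (1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.899), and miR-95-3p had a log2 fold change of 0.38 (edgeR adjusted p = 0.0740). No member passed in the let-7 family (9 tested, median 0.12), the miR-106b-25 cluster (6, 0.03), the miR-200 family (5, 0.35) or the miR-34 family (2, 0.26), with either adjustment (camera adjusted p = 0.601, 0.899, 0.353 and 0.513). The miR-200 list passed camera without DMSO 1 (adjusted p = 0.0399). Of the hypoxia miRNA miR-210, the 3p arm measured 377 ± 38.2 CPM in DMSO and 389 ± 33.2 in CAPE and the 5p arm 5.78 ± 2.21 and 10.3 ± 2.44 CPM, and neither passed over all miRNAs (1 higher when adjusted over the list alone, camera adjusted p = 0.513). Blood, immune, endothelial, muscle and liver miRNAs, markers of serum or of other cells, had none of 6 passing with either adjustment (median -0.09, camera adjusted p = 0.899).

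A final comparison set miRNAs beside the genes that contain them. Over 36 of 43 fixed pairs with both members tested, log2 fold changes of miRNA and host gene gave Pearson's r = -0.13 (permutation p = 0.438, two-sided) and Spearman's rho = -0.17 (permutation p = 0.332), and 17 pairs had the same sign. Without DMSO 3 in the mRNA fit r was 0.07 (permutation p = 0.688). These are correlations across pairs, which are not independent replicates, and no other relation of this kind was computed. miR-425-5p and miR-301a-3p, which fell, lie in DALRD3 and SKA2, whose log2 fold changes were -0.71 and -0.01. VMP1, the host of miR-21-5p, had one of -0.38. Without DMSO 3 DALRD3, SKA2 and VMP1 had values of -0.17, -0.21 and -0.66 (edgeR adjusted p = 0.230, 0.0238 and 1.57e-07). None of these 3 hosts, which were chosen after their values were seen, passed with all 6 libraries.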

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

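The tests of transcript length, of RNA from other cell types and all 3 tests of miR-3960 were chosen after the result was seen, and the reference of DMSO 1 and DMSO 2 in the length test was changed to leave out DMSO 3 after a first result was seen. Dixon's test for a single outlying sample was not run in these groups of 3.

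The mRNA library DMSO 3 lay apart from the other 5, with 2858 genes at least 2-fold lower and 2836 at least 2-fold higher than in DMSO 1 and DMSO 2. Its deviation ran against relative transcript length over 9555 genes (Spearman's rho -0.6219 across genes, which are not independent replicates, against at most 0.271 in size in the other 5), so a length-dependent loss, as in degraded or differently prepared RNA, may be a part of the difference. As the whole difference it is argued against, since the SD of the deviation fell only from 1.09 to 0.858 when the trend was removed, which took 38.1% of the variance, while the other libraries reached at most 0.137. A CAPE library under a DMSO label is argued against by a median position of 0.0199 between DMSO (0) and CAPE (1) over 755 genes (-0.0203 for 580 higher in CAPE, 0.195 for 175 lower), and RNA of a cell type with genes that the other 5 libraries lack by 0 genes at 10 CPM or more in DMSO 3 and under 0.5 CPM in each other library. RNA of an epithelial type whose genes these cells also express stays open, as does the rest of the difference, since the 6 epithelial markers lay a median of 1.96 above DMSO 1 and DMSO 2, with KRT18 at 2.27 but EPCAM at -0.11, and no biological explanation was tested, since the labels give DMSO 3 the same treatment as DMSO 1 and DMSO 2. These 6 markers have short transcripts, at relative lengths of 0.434 to 0.808. In the length deciles with medians of 0.511 to 0.821, genes at large deviated in DMSO 3 by medians of 1.01 to 0.57. A part of the markers' rise may thus follow the length trend.

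miR-3960 rose together with other GC-rich names and names that overlap abundant RNAs. The rest of that list, with miR-3960 left out, had a median log2 fold change of 1.06 (8 of 12 higher). Camera gave p = 2.48e-09 (adjusted p = 2.73e-08), and an adjusted p of 0.0973 with an estimated correlation. The median lies between miR-1260a (1.059) and miR-1260b (1.057), which had similar counts and may share reads. Entries that share reads are not separate evidence, for which the preset correlation of 0.01 hardly allows. Fragments of abundant RNAs counted as miRNAs are thus only a candidate source of the 32 CAPE counts of miR-3960. A response to CAPE stays open beside it and untested. The lower depth of the CAPE libraries is argued against by the raw counts themselves, 32 in CAPE and 1 in DMSO. The smaller share of miR-21-5p in CAPE gives the other miRNAs a rise of 0.148 on the log2 scale in shares of all counts, far below the list's median. That median comes from TMM-scaled counts, which largely take up such a shift, so the comparison could hardly have shown an effect. The median of all miRNAs was 0.0371 with TMM and 0.215 with library totals. With miR-21-5p left out of the fit, miR-3960 still passed, as did 61 of 524 miRNAs in all. CDK9, the gene beside MIR3960 at chromosome 9, 127786034 to 127790792, was chosen after its values were seen and had a log2 fold change of -0.50 (edgeR adjusted p = 0.439), and 0.04 without DMSO 3 (adjusted p = 0.647).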

How the results depend on the processing

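Quality weights, removal of the length trend, robust dispersion, DESeq2 on the edgeR genes and TMM factors, summed miRNA names and leaving out miR-21-5p were chosen after seeing the data. The fitted miR-3960 log2 fold change ran from 4.29 (without DMSO 3) to 6.64 (without DMSO 1) over the alternatives that gave it a value and passed in each, while its 1 and 32 summed counts limit the precision of its size. Without DMSO 1 the DMSO group held 0 counts of it, so the 6.64 depends on the prior count and is no bound. The ratio to a floor of 3 counts over the group was 10.2 there, which leaves out counting error in CAPE, and the exact 95% lower limit was 7.83. Against 265 mRNA genes changed (203 higher, 62 lower, and 241 at least 2-fold, 184 and 57), DESeq2 with its own size factors and filter, which changed both beside the test, gave 857 (530 and 327, and 517, 358 and 159), and on the same genes and TMM factors 991 (661 and 330, and 563, 415 and 148), each with all 265 among them. Quality weights, which gave DMSO 3 a weight of 0.0200 against 2.02 to 2.46, gave 5592 (2915 and 2677, and 821, 631 and 190). TPM with a pseudocount of 1 gave 130 (106 and 24, and 126, 103 and 23), with 0.1 it gave 96 (74 and 22, and 93, 72 and 21), and without a minimum 64 (51 and 13, and 57, 45 and 12). Library totals gave 41 lower and moved the median of all genes to 0.17, and the TPM settings moved it to 0.33, 0.39 and 0.16. Removing the length trend gave 411 genes (130 lower), 211 of them among the 265, and with DMSO 3 left out as well 5835 (2786 and 3049, and 786, 599 and 187). Leaving out 1 library at a time gave 0 to 5731 genes (0 to 2836 higher, 0 to 2895 lower), of which 0 to 795 changed at least 2-fold (0 to 610 and 0 to 185). The replicate number as a block gave 0 mRNA genes (0 higher, 0 lower, 0 at least 2-fold, and 1384 at an unadjusted p under 0.05 in edgeR) and 63 miRNAs. Same-numbered mRNA libraries correlated at -0.34, 0.36 and 0.0018 in their deviations and miRNA libraries at 0.39, 0.0041 and 0.25. The mRNA values cannot decide whether the numbers pair the samples, since DMSO 3 sets them. With CAPE 1, DMSO 1 and DMSO 2 gave -0.34 and -0.36 and DMSO 3 the opposite, 0.36. Among miRNA libraries, DMSO 1 and DMSO 3 correlated most with the CAPE library of their own number, but DMSO 2 with CAPE 1 (0.12), so pairing stays open. The block ended the camera call of the miR-17-92 cluster (adjusted p = 0.0548). At the preset correlation, other settings with all 6 libraries ended the camera calls of metallothioneins (no filter, adjusted p = 0.128), YAP/TEAD targets (0.0534 and 0.0547 with TPM + 1 and TPM + 0.1 at the minimum, 0.0587 with quality weights) and replication-dependent histones (0.0560 with quality weights). Calls were gained for mitochondrially encoded genes (totals, unfiltered TPM and quality weights, adjusted p = 0.0323, 0.0231 and 0.00140) and epithelial markers (totals, TPM + 1 and TPM + 0.1 at the minimum, 0.0430, 0.020 and 0.0248). The MYC log2 fold change ran from -0.63 to -0.268 over single libraries left out and passed at -0.268 without DMSO 3, -0.27 with quality weights and -0.264 with the length trend and DMSO 3 removed. The YAP1 log2 fold change turned to -0.0786, -0.070 and -0.101 under the same settings, with 0.39 as its highest value over single libraries left out, and the host pair correlation turned to 0.0698 without DMSO 3. Among miRNAs, against 62 changed (39 higher, 23 lower, and 18 at least 2-fold, 17 and 1), library totals gave 67 higher and 8 lower. A minimum of 10 CPM gave 10 at least 2-fold (10 and 0), no filter gave 3 at least 2-fold lower, and both DESeq2 settings and limma-voom gave 0. Leaving out 1 library gave 17 to 128 (14 to 60 higher, 3 to 68 lower), of which 13 to 32 changed at least 2-fold (13 to 23 and 0 to 9). The other directions that turned were of values past no threshold, except the miR-17-92 list. PSMC6 was 0.0437, 0.0443 and 0.0437 under the TPM settings. The median of G1/S and DNA replication was 0.0536 with totals, 0.0489 with weights, 0.232, 0.234 and 0.232 under TPM, and -0.257 to 0.0486 over single libraries left out. The median of autophagy and lysosome was 0.0017 with weights, 0.218, 0.227 and 0.218 under TPM, and -0.343 to 7.37e-04 over single libraries. That of NRF2 targets was 0.0725 with weights, 0.0733 with TPM + 0.1, 0.153 with unfiltered TPM, and -0.379 to 0.0667 over single libraries. The fibroblast median was -0.169 with weights and -0.184 to 0.214 over single libraries, that of neuroendocrine SCLC markers -0.0284 with RLE and -0.109 to 0.403, and that of the pro-apoptotic list -0.0226 to 0.181. With totals hsa-let-7i-5p was 0.0489 and hsa-miR-106b-3p 0.00899. Over single libraries hsa-let-7f-5p ran from -0.0324 to 0.255 and hsa-miR-210-3p from -0.0461 to 0.0984, with -0.042 without a filter. The median of miR-106b-25 cluster was -0.00733 with RLE, -0.056 without a filter, -0.0129 with DESeq2, -0.00615 without miR-21-5p and -0.0585 to 0.0603 over single libraries. The median of miR-17-92 cluster was 0.0219 with totals, and that of the blood and serum miRNAs 0.10 with totals and 0.011 at a minimum of 10 CPM. The median of neuroendocrine miRNAs was -0.168 at that minimum and -0.0424 to 0.357 over single libraries, and that of the let-7 family -0.069 to 0.184. The cause was not tested, except that leaving out a library leaves fewer samples.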

Other observations

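The genes and the test of aryl hydrocarbon receptor targets given here were chosen after their values were seen. Further members of the fixed hypoxia list (NDRG1, VEGFA and ADM) and ATF4 list (CHAC1 and DDIT3) rose with CAPE. They are already in the counts given for those lists and add no separate evidence. With all 6 libraries 8 of 21 hypoxia members and 10 of 24 ATF4 members were higher, and the rest did not pass. NDRG1, a stress-responsive gene induced by hypoxia, rose from 214 ± 70.0 to 1044 ± 26.3 CPM (SD, n = 3), VEGFA, the angiogenic growth factor, from 133 ± 28.9 to 362 ± 18.3 CPM, and ADM, the peptide hormone adrenomedullin, from 29.4 ± 8.62 to 150 ± 3.71 CPM. CHAC1 and DDIT3, both targets of the ATF4 response, had log2 fold changes of 2.68 and 2.20 (edgeR adjusted p = 0.0353 and 0.0106). ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, rose from 21.1 ± 4.20 to 154 ± 13.6 CPM. WNT5A, a secreted signalling protein, fell from 682 ± 200 to 238 ± 11.6 CPM, and AXIN2, a target and inhibitor of Wnt signalling, fell by 1.48 on the log2 scale (edgeR adjusted p = 0.0407). Without DMSO 3 the log2 fold changes were 2.58 for NDRG1, 1.27 for VEGFA, 2.62 for ADM, 3.23 for CHAC1, 2.32 for DDIT3, 2.72 for ERRFI1, -1.75 for WNT5A and -1.64 for AXIN2, all passing.

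Neuroendocrine markers differed from one another in level in the 6 mRNA libraries. ENO2 ran from 37.5 to 204 CPM, UCHL1 from 6.39 to 12.9, DLL3 from 0.227 to 1.39 and SYP from 0.506 to 0.765, by library totals. NEUROD1, INSM1, CHGA and NCAM1 had at most 2 counts in any library, and GRP and MYCN had 0, which allows up to 3 counts. KRT7, an epithelial keratin, ran from 1144 to 3725 CPM and VIM, the mesenchymal filament protein, from 1007 to 1902 CPM, by library totals. RB1, the tumour suppressor, ran from 0.0956 to 1.30 CPM, and miR-375-3p, a neuroendocrine miRNA, had 1 count in all. The outlying mRNA library DMSO 3 held the highest values of KRT7, VIM, UCHL1 and DLL3 and the lowest of RB1. The ENO2 range includes its rise with CAPE.

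CYP1B1 and AHRR were among the 10 largest falls, and lower activity of the aryl hydrocarbon receptor is a hypothesis for them, since both are its targets. Of 8 tested genes of a short target list 7 were lower without DMSO 3, where 2895 of all 13919 genes were lower. Their median log2 fold change was -0.81 (camera p = 7.54e-05, and p = 0.0495 with an estimated correlation), and some falls were small (NQO1 -0.12, NFE2L2 -0.39). With all 6 libraries 2 of 8 were lower, and 4 when adjusted over the list alone. The median there was -1.12 (camera p = 2.64e-05, and p = 0.0122 with an estimated correlation). In the fit without DMSO 3 CYP1A1 fell by 2.59 (SE 0.42) and TIPARP by 1.04 on the log2 scale, while LPCAT2 had a log2 fold change of -0.09 that did not pass. CYP1A1 lay near the floor, at an average log2 CPM of 0.25, so the size of its fall is imprecise. The list includes CYP1B1 and AHRR, from which the hypothesis came, and other causes of lower mRNA were not tested, so the 7 lower genes may have fallen for another reason.

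Among the 10 ways to split 6 libraries into groups of 3, the real one gave 265 mRNA genes and the highest other 0, so 1 split reached the real value. For miRNA it was 62 and 0, again 1 split of 10. With 10 splits the share is never under 0.1, too few for a share under 0.05.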
